A study of Mus musculus with 12 samples.

How the data were processed

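Total RNA from mouse liver, 12 samples, was converted to polyadenylated RNA libraries and sequenced, per the labels' protocols. The groups are ligated mice without and with HDCA and Abcb4-null mice without and with HDCA, 3 samples each, taken from the sample titles and the design text of the series. Samples titled MDR were read as the Abcb4-null model because the design text names no other. The series has a single processed table with 1 column per sample, all 12 of which were mapped to a group. The deposited values are FPKM, fragment numbers scaled by the authors for gene length and for the assigned fragments of each library. Per the submitters' processing notes, the tools were CASAVA 1.8, fastp, HISAT2 2.0.5, featureCounts 1.5.0-p3 and DESeq2 1.20.0, on GRCm38 (mm10). The notes give no role or order of these tools and no release of the gene annotation. Whether strand was used in counting is not stated, so genes overlapping on opposite strands are uncertain.

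The table holds 16970 genes. The authors' FPKM values were checked for an underlying whole number of fragments. Gene lengths and the assigned fragments of each library were solved from the values, and 16942 genes (99.8%) then gave whole fragments in all 12 libraries within a tolerance of 0.05, against 0 of 500 genes with scrambled values. Solved depths were 34.3 to 40.5 M fragments per library, of which 99.6% to 99.8% lay in the table. Sums of FPKM were 460650 to 491265, genes at 0.1 FPKM or more numbered 12296 to 13832, and the 10 highest genes took 16.6% to 23.3% of FPKM. The recovered fragments were used for limma-voom as an alternative and for depth. No pair of libraries of a group was a duplicate, since their fragment counts differed by a chi-square per degree of freedom of 39.4 to 517. Gene symbols are those of the table, and positions are from GENCODE M21 on GRCm38, to which 16394 genes (96.6%) matched by symbol. Of these 98.6% are protein coding. The solved lengths equal the M21 exon union in 1.52% of tested genes, so the authors' gene models are another set, and M21 was used for positions alone.

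FPKM was transformed as log2(FPKM + 1), with a pseudocount of 1, and genes with a mean of at least 1 FPKM over the 12 libraries were kept, 10317 genes. The linear models of limma 3.58.1 in R 4.3.3 were fitted with 1 mean per group over all 12 libraries, so that all groups share an estimate of the spread. Variances were moderated with a mean-variance trend, tests were two-sided, and p-values were adjusted by Benjamini-Hochberg within each comparison, with a threshold of 0.05. The comparisons were HDCA in ligated mice, HDCA in MDR-labelled mice, the difference of these effects, and untreated ligated minus untreated MDR-labelled mice. The p-values of single genes measure the spread between these samples. Those of the list tests at a preset correlation, described below, compare the genes of a list with the other genes and do not measure that spread. The labels do not say in words that each sample is a separate mouse. Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3 read the table and solved the depths.

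Gene lists of pathways and cell type markers, 31 in number, were fixed with the designs, the alternatives and the rule for named genes before the data were examined. They hold 461 entries, of which 444 are in the table and 382 were tested. The 26 lists with at least 5 tested members were tested with camera at a preset inter-gene correlation of 0.01, with adjustment over the lists of each comparison. An estimated correlation and fry were alternatives. The named genes are the 10 largest increases and 10 largest decreases past the threshold whose groups do not overlap. With fewer than 5 passing in a direction, the 5 with the smallest p are named as not passing. In lists that passed, the 4 members with the smallest p could be named. Abcb4, Etv4, Cyp7a1, Cyp8b1, Nr0b2, Abcb11, Slc51b, Col1a1, Acta2, Timp1, Krt19 and Tnf were named whatever their values, and clone or predicted genes were left out. The Y-linked genes and the wider spread of Cyp2c40 and Cyp2c69 per library were described after their values were seen.

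Replicate numbers are shared between groups, so the correlation of same-numbered deviations from group means was computed. In the MDR-labelled groups it was 0.445, 0.312 and 0.564, and every library correlated best with its own number. The numbers were therefore treated as possible pairs there, with no word on it in the labels. With 3 samples per group such a match can also arise by chance. Pair 1 joins MDR 1, which has Y-linked transcripts, with MDR HDCA 1, which does not.

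The steps were tested on simulated data with independent genes, 10317 genes in 5 runs with 100 genes changed per size and run. At 1 log2 unit, 75.2% of changed genes were recovered for HDCA in ligated mice, 72.0% for HDCA in MDR-labelled mice, 43.4% for the difference of effects and 72.2% between the untreated models. At 2 log2 units these were 94.8%, 93.2%, 87.4% and 95.4%. False calls were 6.08%, 4.51%, 5.49% and 4.66% of those called. A list shifted by 0.5 was called in 5, 5, 4 and 5 of 5 runs. Real genes of a list vary together and some real libraries stand apart from their group, which the simulation leaves out.

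Alternatives chosen beforehand were pseudocounts of 0.1 and 0.5, no filter and a filter at 5 FPKM, TPM, median-of-ratios and quantile scaling, a replicate block, fits of the compared groups alone, other variance moderation, array weights, a fold threshold, and each library left out in turn. Added after the data were seen were leaving out BDL 1 with BDL HDCA 2, a term for Y-linked transcripts (mean of 4 Y-linked genes above 1 FPKM), the replicate block with each MDR-labelled pair left out, limma-voom on recovered fragments, list tests under further scalings, and array weights by the gene-by-gene method. The default array weight estimation stopped before converging. A protein-coding subset was not run, because the table gives no biotype.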

Results

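Liver polyadenylated RNA was sequenced from 12 mouse samples in 4 groups of 3. Cholestasis was modelled by 7-day bile duct ligation (BDL) or by loss of Abcb4, the canalicular phospholipid transporter. In each model, 3 samples came from mice given hyodeoxycholic acid (HDCA), a secondary bile acid, at 100 mg/kg, and 3 came from mice listed without it. HDCA was given for 4 days, from 3 days after surgery, in the ligated mice. It was given for 21 days in 60-day-old Abcb4-null mice. The sample titles of that model read MDR, and Mdr2 is an older name of Abcb4, so these libraries are called MDR-labelled here. Libraries are named by group and number (BDL 1, BDL HDCA 1, MDR 1, MDR HDCA 1). No sham-operated or healthy wild-type group is among the 12 samples, so no comparison is with a group listed as healthy. The libraries held between 34.3 M (MDR HDCA 1) and 40.5 M (BDL HDCA 3) assigned fragments (M, mega), recovered from the values. At that depth a single fragment on a 1 kb gene equals 0.0247 to 0.0292 FPKM. Values after ± are the SD for group means and the SE for log2 differences, with n = 3 per group.

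Abcb4 transcript was present in every library, including those labelled as null. The ligated libraries held 52.8, 152 and 168 FPKM of Abcb4 without HDCA, and 160, 72.1 and 178 FPKM with it. The MDR-labelled libraries held 181, 150 and 162 FPKM without HDCA, and 165, 155 and 129 FPKM with it. Group means of Abcb4 were 124 ± 62.3, 137 ± 56.9, 164 ± 15.7 and 150 ± 18.6 FPKM in the same order. The transcript total of Abcb4 (chromosome 5, 8893717 to 8959231, GRCm38) thus does not bear out the null genotype, and the gene-level value cannot show whether a part of the transcript was missing. Directions drawn below from the MDR-labelled libraries rest on the titles alone.

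Y-linked transcripts followed the model in 11 of the 12 libraries. Ddx3y, a Y-chromosome RNA helicase, lay between 9.35 and 11.0 FPKM in all 6 ligated libraries and at 10.5 FPKM in MDR 1. It was between 0 and 0.00523 FPKM in the other 5 MDR-labelled libraries. The labels give no sex. The mean of Ddx3y, Eif2s3y, Kdm5d and Uty split the libraries in the same way, 7 with Y-linked transcripts and 5 without.

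**Figure D1:**
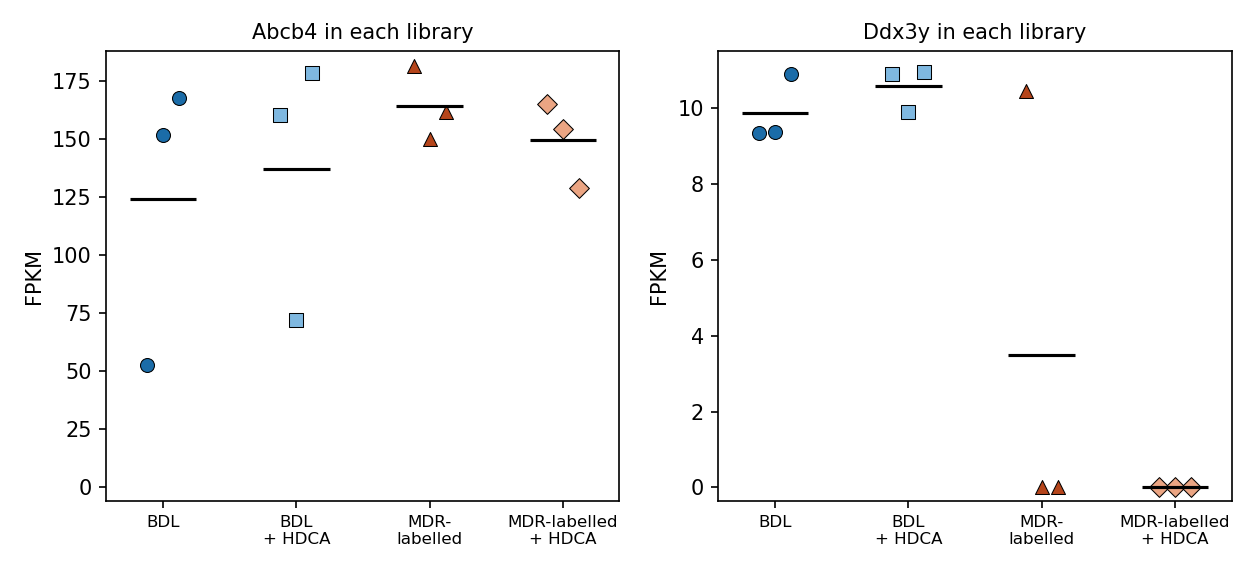
FPKM of Abcb4 (left) and of the Y-linked gene Ddx3y (right) in each of the 12 libraries, by group, with a line at the group mean. Abcb4 lies at 129 FPKM or above in all 6 MDR-labelled libraries, and Ddx3y is near 0 in 5 of them.

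Across the 10317 genes tested, the first principal component held 52.2% of the variance and placed all 6 ligated libraries on one side and all 6 MDR-labelled libraries on the other. The second held 21.0%. BDL 1 and BDL HDCA 2 stood apart from the other ligated libraries, with first-component scores of 49.0 and 43.3 and median correlations with their own model of 0.957 and 0.970. The remaining 4 ligated libraries had median correlations of 0.991 to 0.993. The depth of these libraries, 39.2 and 39.9 M fragments, lay within the range of the rest. They had the fewest genes at 0.1 FPKM or more (12296 and 12639, against 12848 to 13832) and the lowest median FPKM of tested genes (5.05 and 5.29, against 6.46 to 7.86). Their FPKM sums, 484156 and 490185, were the highest of the ligated libraries.

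**Figure D2:**
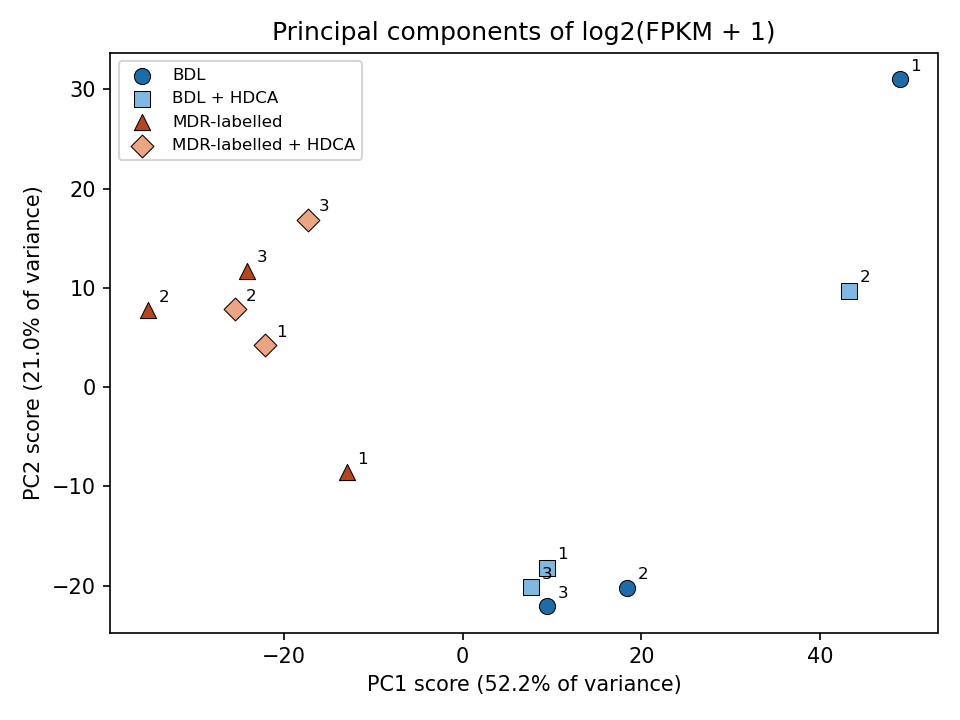
Scores of the 12 libraries on the first principal components of log2(FPKM + 1), with the share of variance on each axis and the replicate number beside each point. BDL 1 and BDL HDCA 2 lie at 49.0 and 43.3 on the first component, apart from the other ligated libraries.

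The effect of HDCA after bile duct ligation was examined first. Markers of endothelial cells, of stellate cells and myofibroblasts, and collagens with other matrix genes were higher as groups in the HDCA-treated ligated livers, and cholesterol synthesis genes were lower as a group, by a test with a preset correlation between genes. With an estimated correlation none of these 4 lists passed (adjusted p = 0.80, 0.80, 0.92 and 0.92), and the cholesterol synthesis median turned to +0.10 without BDL HDCA 2. All 11 endothelial markers had positive differences, with a list median of +0.77 on the log2 scale. Lyve1 and Stab1, a hyaluronan receptor and a scavenger receptor of liver sinusoidal endothelium, differed by +1.00 ± 0.31 and +0.89 ± 0.29, and Pecam1 by +0.79 ± 0.33. All 14 stellate cell and myofibroblast markers were also positive, with a median of +0.45. Acta2, the smooth muscle actin of activated stellate cells, averaged 2.91 ± 1.98 FPKM without HDCA and 8.15 ± 5.08 FPKM with it, a difference of +1.23 ± 0.45. Tagln and Myl9, contractile proteins of the same list, differed by +1.02 ± 0.39 and +0.81 ± 0.29. No single gene named in this paragraph passed the test on its own.

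By camera, limma's competitive gene set test with a preset inter-gene correlation, 6 of 26 lists passed for HDCA in the ligated mice. The adjusted p was 1.03e-10 for endothelial markers and 1.57e-07 for stellate cell and myofibroblast markers, each with adjusted p = 0.80 with an estimated correlation. Collagens and matrix genes had a median of +0.46, with 16 of 18 members positive (adjusted p = 1.78e-04). With an estimated correlation the adjusted p was 0.92. Within that list the fibrillar collagen chains Col3a1 and Col1a2 differed by +1.03 ± 0.49 and +0.81 ± 0.36, and fibronectin (Fn1) by -0.28 ± 0.12. Erythroid markers, mainly globins, had a median of +0.57 with 5 of 5 positive (adjusted p = 0.0139, and adjusted p = 0.92 with an estimated correlation). Cholesterol synthesis genes had a median of -0.30 with 22 of 24 members negative (adjusted p = 2.26e-06, and adjusted p = 0.92 with an estimated correlation). The farnesyl diphosphate synthase gene Fdps differed by -0.58 ± 0.37 and the sterol demethylase gene Cyp51 by -0.52 ± 0.35. The ER stress list passed as lower (adjusted p = 0.0472, and adjusted p = 0.96 with an estimated correlation), with a mean of -0.12 but a median of +0.03. Its leading members Ddit3 and Trib3 differed by -0.64 ± 0.26 and -0.61 ± 0.23. Over each of the 26 lists 0 genes passed by limma, both over all genes and adjusted over the list alone.

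Libraries standing apart moved with these lists. The endothelial list mean was 1.96 in BDL 1 against 3.06 and 3.65 in the other untreated ligated livers, and the cholesterol synthesis mean was 4.82 in BDL HDCA 2 against 5.98 and 6.04 in the other treated ones. Without BDL HDCA 2 the cholesterol synthesis median turned to +0.10 (adjusted p = 0.98), without BDL 1 it was -0.31 (adjusted p = 0.202), and without both it was +0.11 (adjusted p = 0.0103). The collagen call ended without BDL HDCA 3 (median +0.23, adjusted p = 0.0908). The erythroid call ended without BDL 1 (median +0.14, adjusted p = 0.286) and without BDL HDCA 1 (median +0.36, adjusted p = 0.140). The ER stress call ended without BDL 2, BDL 3 or BDL HDCA 3 (adjusted p = 0.730, 0.0617 and 0.245), and under each other scaling (adjusted p = 0.0712 to 0.169), with a pseudocount of 0.1 (0.0744) and with a filter at 5 FPKM (0.885). The number of lists past the threshold was 6 with all libraries, 13 without BDL 1, 15 without BDL HDCA 2 and 12 without both. The endothelial and stellate cell calls held in each of these leave-one-out fits, but their sizes rested on single libraries. The endothelial median was +0.22 without BDL 1 and +1.15 without BDL 3, against +0.77 with all libraries. The stellate cell median was +0.23 without BDL 1, +0.25 without BDL HDCA 3 and +0.69 without BDL 3, against +0.45. Of calls that held elsewhere, the collagen median was +0.28 without BDL 1, the erythroid median +0.87 without BDL HDCA 2, and the cholesterol synthesis median -0.52 without BDL HDCA 1 and -0.59 without BDL HDCA 3. The ER stress median was -0.21 without BDL 1, -0.09 without BDL HDCA 1 and +0.07 without BDL HDCA 2.

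These libraries also differed in lists that did not pass or were not tested. The mean of the macrophage list was 3.33 in BDL 1 and 3.43 in BDL HDCA 2, against 4.21 to 4.70 in the other 4 ligated libraries, and that of the cell cycle list 0.811 and 1.30 against 2.41 to 2.83. The 1 adipocyte marker above the expression filter was at 3.44 in BDL HDCA 2, against 1.37 to 2.20 in the other 5 ligated libraries, on the log2(FPKM + 1) scale.

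Among single genes, Gpihbp1, the lipoprotein lipase anchor of capillary endothelium (chromosome 15, 75596628 to 75599481), had the smallest p. It averaged 14.5 ± 6.26 FPKM without HDCA and 32.3 ± 0.166 FPKM with it, a log2 difference of +1.2 ± 0.25. The next were the chemokine Ccl21a (+1.21 ± 0.28), the Wnt antagonist Sfrp1 (+0.56 ± 0.13), the procollagen peptidase Adamts2 (+0.75 ± 0.18) and the lectin Colec10 (+0.76 ± 0.19). In the other direction stood the hepatokine Fgf21, which averaged 11.2 ± 5.30 FPKM without HDCA and 2.08 ± 0.207 FPKM with it (-1.89 ± 0.56). With it came the neutrophil protease gene Prtn3 (-0.67 ± 0.16), the chemokine Ccl24 (-0.91 ± 0.26), Cbr3 (-0.44 ± 0.13) and Snx21 (-0.40 ± 0.12). Each of these 10 genes had an adjusted p of 1.00. By limma 0 of 10317 genes passed, 229 had an unadjusted p under 0.05 where 516 would by chance, and limma-voom on recovered fragments also gave 0, with 233 at an unadjusted p under 0.05. With array weights Gpihbp1 alone passed (adjusted p = 0.00682). The treated and untreated values did not overlap for 511 genes, 4.95%, where chance gives 10%. In simulated data with independent genes, 75.2% of genes changed by 1 log2 unit and 94.8% of those changed by 2 were recovered for this comparison. The simulated libraries did not include any that stand apart, so these shares do not show that changes of that size would have been found here.

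No gene of bile acid handling named here passed. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, was at 72.8, 8.87 and 14.8 FPKM in BDL 1, BDL 2 and BDL 3, so that BDL 1 carries the untreated mean of 32.1 ± 35.3 FPKM. Treated ligated livers averaged 28.6 ± 6.38 FPKM. The log2 difference of Cyp7a1 was +0.37 ± 0.57 and ran from -0.22 without BDL 2 (adjusted p = 0.995) to +1.23 without BDL 1 (adjusted p = 0.985). With array weights it was +1.59 (adjusted p = 0.0844), so its direction is not settled. Cyp8b1, the sterol 12-alpha-hydroxylase, averaged 108 ± 82.5 and 149 ± 87.6 FPKM. Nr0b2, the repressor SHP induced by bile acids through FXR, averaged 39.0 ± 11.4 and 25.3 ± 15.1 FPKM (-0.81 ± 0.44). The bile salt export pump Abcb11 averaged 148 ± 51.8 and 154 ± 83.9 FPKM, and the basolateral transporter subunit Slc51b 13.3 ± 7.25 and 15.4 ± 8.38 FPKM. Among markers of injury and repair, Col1a1 averaged 10.9 ± 1.96 and 20.5 ± 11.7 FPKM, Timp1 6.04 ± 0.309 and 6.98 ± 3.90 FPKM, and the ductular keratin Krt19 5.53 ± 0.978 and 6.50 ± 2.11 FPKM. Etv4 (0.102 and 0.138 FPKM) and Tnf (0.474 and 0.680 FPKM) lay below the expression filter and were not tested.

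In the MDR-labelled mice given HDCA for 21 days, cholangiocyte, collagen, globin and respiratory chain lists were lower and 4 lists of hepatocyte functions slightly higher, by the test with a preset correlation. With an estimated correlation none passed (adjusted p = 0.914 for each), and the 4 higher lists did not pass under median-of-ratios or quantile scaling. Of 11 cholangiocyte markers, 10 were negative, with a median of -0.27. Krt7 differed by -0.27 ± 0.19 and the biliary transcription factor Sox9 by -0.29 ± 0.20. Of 18 collagen and matrix genes, 17 were negative (median -0.23), among them Fn1 at -0.25 ± 0.12 and Col6a3 at -0.43 ± 0.34. Fatty acid oxidation genes controlled by PPAR alpha were positive in 16 of 21 members, with a median of +0.05, led by the fatty acid hydroxylase Cyp4a14 at +1.21 ± 1.1. Glucose metabolism genes had a median of +0.16, with the gluconeogenic enzyme Pck1 at +0.73 ± 0.53.

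By camera 8 of 26 lists passed for HDCA in the MDR-labelled mice, and all 8 had adjusted p = 0.914 with an estimated correlation. The adjusted p was 0.00838 for cholangiocyte markers, 0.0110 for collagens and matrix, 0.0474 for erythroid markers (median -0.34, 0 of 5 positive) and 0.0474 for the respiratory chain (median -0.08, 2 of 14 positive). It was 0.0166 for PPAR alpha targets, 0.0327 for glucose metabolism, 0.0327 for hepatocyte markers (median +0.06, 13 of 18 positive) and 0.0441 for acute phase proteins (median +0.06, 12 of 18 positive). With the replicate number as a block the respiratory chain call ended (adjusted p = 0.0941). The 4 higher lists did not pass under median-of-ratios scaling (adjusted p = 0.158 to 0.252) or quantile normalization (0.255 to 0.895), the respiratory chain not under median-of-ratios scaling (0.518), the erythroid list not as TPM (0.0514) and the acute phase list not with a filter at 5 FPKM (0.0548). Over each list 0 genes passed, both over all genes and adjusted over the list alone.

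Leaving out 1 library, which also breaks a pair of numbers, ended each of these 8 calls at least once. The number of lists past the threshold fell from 8 to 2 without MDR 2, 3 without MDR HDCA 3, 4 without MDR 1, and 5 without MDR 3 or MDR HDCA 2. The cholangiocyte call ended without MDR 2 (median -0.05, adjusted p = 0.548) and MDR HDCA 1 (-0.16, adjusted p = 0.637). The collagen call ended without MDR 2 (-0.11, adjusted p = 0.387) and MDR 3 (-0.19, adjusted p = 0.228), and its tested direction turned without MDR HDCA 1 (median -0.06, adjusted p = 0.513). The erythroid call ended without MDR 1, MDR 2, MDR 3, MDR HDCA 1 or MDR HDCA 2 (adjusted p = 0.0585, 0.265, 0.0993, 0.275 and 0.733). The respiratory chain call ended without MDR 1, MDR 3 or MDR HDCA 3 (adjusted p = 0.888, 0.0536 and 0.324), and its tested direction turned without MDR HDCA 2 (median -0.02, adjusted p = 0.738). The PPAR alpha call ended without MDR 1, MDR 2 or MDR HDCA 2 (adjusted p = 0.0650, 0.548 and 0.0592) and turned without MDR HDCA 3 (-0.09, adjusted p = 0.541). The glucose call ended without MDR 1 or MDR 2 (adjusted p = 0.0650 and 0.764) and turned without MDR HDCA 3 (-0.03, adjusted p = 0.772). The hepatocyte call ended without MDR 1, MDR 2 or MDR HDCA 3 (adjusted p = 0.0585, 0.438 and 0.541), and the acute phase call without MDR 1, MDR 2, MDR HDCA 2 or MDR HDCA 3 (adjusted p = 0.0650, 0.548, 0.243 and 0.380). Where the call held, the cholangiocyte median was -0.43 without MDR HDCA 2, and the collagen median -0.42 without MDR 1 and -0.44 without MDR HDCA 2. The respiratory chain median was -0.17 and the glucose median +0.08 without MDR HDCA 1, the PPAR alpha median +0.12 without MDR 3 and +0.22 without MDR HDCA 1, and the acute phase median +0.16 without MDR 3.

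The replicate numbers may pair the MDR-labelled libraries, so list means were also compared within pairs 1, 2 and 3, treated minus untreated. The sign was the same in all 3 pairs for 6 of 26 lists, where independent signs would give 6.5. Cholangiocyte markers differed by -0.27, -0.29 and -0.25 and collagens by -0.16, -0.14 and -0.37. Glucose metabolism genes differed by +0.06, +0.37 and +0.20, and the other 5 lists called above had 1 pair opposite to the rest. Cell cycle, circadian clock and NRF2 lists, which did not pass, were negative in all 3 pairs (-0.14, -0.22 and -0.17, then -0.06, -0.11 and -0.18, then -0.33, -0.03 and -0.37). With the number as a block and pairs 1, 2 and 3 left out in turn, the cholangiocyte call held (adjusted p = 0.0130, 0.00323 and 3.97e-04), as did the collagen call (0.0130, 7.05e-06 and 0.0167). Without the block and with all libraries, neither passed with an estimated correlation, as given above. The blocked fits were not run with an estimated correlation. The other 6 calls ended without pair 2 (MDR 2 and MDR HDCA 2, adjusted p = 0.176 to 0.874). Without pair 3 the acute phase, hepatocyte, PPAR alpha and respiratory chain calls ended (adjusted p = 0.0672 to 0.265), and without pair 1 the erythroid call (0.182).

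The single genes with the smallest p in the MDR-labelled mice were led by the growth factor gene Igf1 (chromosome 10, 87858265 to 87937042). Igf1 averaged 54.3 ± 7.42 FPKM without HDCA and 76.2 ± 2.68 FPKM with it, a log2 difference of +0.49 ± 0.13. Cyp2c40 and Cyp2c69, neighbouring P450 genes on chromosome 19 with higher expression in female mouse liver, differed by +3.30 ± 0.96 and +3.35 ± 1.08. Their values varied widely within groups. Cyp2c40 was 0.0784, 1.66 and 13.1 FPKM in MDR 1, MDR 2 and MDR 3, and 7.59, 39.5 and 111 FPKM in MDR HDCA 1, MDR HDCA 2 and MDR HDCA 3. MDR 1, the lowest of them, is the only one of the 6 with Y-linked transcripts. With the replicate number as a block and pair 1 left out, Cyp2c69 passed (+4.08, adjusted p = 0.00485), the only such call. Also positive were Tcim (+0.67 ± 0.21) and the transglutaminase gene Tgm1 (+0.55 ± 0.18). Negative were Dnajc17 (-0.54 ± 0.16), Olig1 (-0.88 ± 0.29), Mettl1 (-0.44 ± 0.15), Galk1 (-0.33 ± 0.11) and the glycolytic enzyme gene Gapdh (-0.36 ± 0.12). Each of these 10 genes had an adjusted p of 1.00.

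By limma 0 of 10317 genes passed in the MDR-labelled mice, with 51 at an unadjusted p under 0.05 where 516 would by chance. Limma-voom gave 0, with 44. The limma spread was shared by all groups, including BDL 1 and BDL HDCA 2, and the median SE was 0.166 for HDCA in either model. The count of 0 therefore does not show that HDCA had no effect in the MDR-labelled mice. Groups did not overlap for 613 genes, 5.94%. Chance gives 10% for unpaired samples, a share that does not hold if the numbers mark pairs. Cyp7a1 averaged 18.1 ± 5.62 FPKM without HDCA and 27.6 ± 5.60 FPKM with it (+0.61 ± 0.57), and Cyp8b1 139 ± 81.2 and 185 ± 43.1 FPKM (+0.56 ± 0.58). Nr0b2 averaged 16.4 ± 3.95 and 10.4 ± 1.78 FPKM (-0.60 ± 0.44), Slc51b 7.41 ± 3.00 and 4.56 ± 1.67 FPKM, and Abcb11 137 ± 4.90 and 117 ± 13.0 FPKM. Col1a1 averaged 21.1 ± 7.83 and 15.6 ± 7.30 FPKM, Acta2 3.35 ± 1.00 and 3.69 ± 0.364 FPKM, Timp1 10.2 ± 2.75 and 9.26 ± 2.74 FPKM, and Krt19 14.3 ± 5.43 and 11.7 ± 3.24 FPKM. Etv4 (0.0604 and 0.111 FPKM) and Tnf (0.852 and 0.860 FPKM) were below the filter.

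The HDCA effects of the models were then compared with each other, as the ligated difference minus the MDR-labelled difference. Among the lists that passed with a preset correlation, the largest medians of this difference were +0.94 for erythroid markers, +0.75 for endothelial markers, +0.62 for collagens and matrix and +0.51 for stellate cell and myofibroblast markers. None of them passed with an estimated correlation (adjusted p = 0.81). Male-biased liver genes had a median of +0.78, with 11 of 11 positive, and did not pass (adjusted p = 0.234). All 11 endothelial, all 14 stellate cell, all 5 erythroid and 16 of 18 collagen genes were positive. Vwf, the endothelial clotting factor, differed between the effects by +0.68 ± 0.30, Col3a1 by +1.39 ± 0.69 and Tagln by +1.2 ± 0.55. Duration of dosing differed between the models, so the model and the length of treatment are not separated here. Y-linked transcripts were in all ligated libraries but, of the MDR-labelled ones, in the untreated MDR 1 alone. The difference of effects is thus not separated from the sex mix either. The male-biased list mean differed within the possible MDR-labelled pairs by -1.63, +0.49 and +0.15, the first being the pair with MDR 1.

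By camera 9 of 26 lists passed for the difference of effects, all with adjusted p = 0.81 with an estimated correlation. The adjusted p was 1.71e-05 for both collagens and endothelial markers, 2.52e-04 for stellate cell markers and 0.00288 for erythroid markers. It was 0.0105 for cholesterol synthesis (median -0.10), 0.0181 for ER stress (lower by the test and by its mean of -0.12, median +0.06) and 0.0386 for cholangiocyte markers (median +0.37), respiratory chain (+0.13) and acute phase proteins (-0.10). Over each list 0 genes passed, both over all genes and adjusted over the list alone. With the replicate number as a block the acute phase and respiratory chain calls ended (adjusted p = 0.0711 and 0.0743).

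Leaving out 1 library moved most of these differences of effects, and for MDR-labelled libraries it may also break a pair. The collagen, endothelial and stellate cell calls held in every such fit. The endothelial median was +0.31 without BDL 1 and +1.14 without BDL 3, against +0.75 with all libraries. The stellate cell median was +0.33 without BDL 1, +0.32 without MDR 2 and +0.78 without MDR 1, against +0.51. The erythroid median was +0.54 without BDL 1, and the call ended without MDR HDCA 2 (median +0.80, adjusted p = 0.0520). The cholesterol synthesis call turned without BDL HDCA 2 (+0.22, adjusted p = 0.152) and ended without BDL 1, MDR 3 or MDR HDCA 2 (adjusted p = 0.617, 0.0713 and 0.211). Where it held, its median was -0.33 without BDL HDCA 1, -0.39 without BDL HDCA 3, -0.19 without MDR 2 and -0.17 without MDR HDCA 1. The acute phase call turned without BDL HDCA 1 (+0.18, adjusted p = 0.0650) and ended without BDL 1, BDL HDCA 3, MDR 2, MDR HDCA 2 or MDR HDCA 3 (adjusted p = 0.830, 0.105, 0.249, 0.142 and 0.184). Where it held, its median was -0.20 without BDL 3, -0.36 without BDL HDCA 2 and -0.01 without MDR 1. The cholangiocyte call ended without BDL 2, BDL HDCA 2, BDL HDCA 3, MDR 2, MDR HDCA 1 or MDR HDCA 3 (adjusted p = 0.0914, 0.0865, 0.105, 0.440, 0.619 and 0.0521), and its median was +0.23 without BDL 1. The ER stress call ended without BDL 2, BDL HDCA 3, MDR 2 or MDR HDCA 2 (adjusted p = 0.321, 0.105, 0.136 and 0.138), and its median ran from -0.25 without BDL 1 to +0.13 without BDL HDCA 2 where it held. The respiratory chain call ended without BDL 2, BDL 3, BDL HDCA 1, BDL HDCA 2, MDR 1, MDR HDCA 2 or MDR HDCA 3 (adjusted p = 0.242, 0.457, 0.0859, 0.305, 0.303, 0.699 and 0.119), and its median was +0.22 without MDR HDCA 1. Without MDR HDCA 2, 4 lists passed. Under median-of-ratios scaling the ER stress, acute phase and respiratory chain calls ended (adjusted p = 0.0512, 0.358 and 0.502), and under quantile normalization the ER stress, acute phase and cholesterol synthesis calls (0.156, 0.628 and 0.221). With a filter at 5 FPKM the ER stress and acute phase calls ended (0.376 and 0.0988). Without BDL 1 and BDL HDCA 2 together, the cholesterol synthesis median was +0.27 (adjusted p = 8.58e-04) and the cholangiocyte call ended (0.0915).

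The gene with the smallest p for the difference of effects was Igf1 (-0.87 ± 0.18), which averaged 59.7 ± 7.34 FPKM in untreated and 45.6 ± 3.14 FPKM in treated ligated livers. Cda (-0.79 ± 0.18), Prtn3 (-0.95 ± 0.23), Snx21 (-0.67 ± 0.16) and Atoh8 (-0.87 ± 0.23) were also negative. Adamts2 (+0.96 ± 0.26), C1qtnf6 (+0.80 ± 0.23), Ccl21a (+1.34 ± 0.39), Tbc1d16 (+0.56 ± 0.17) and the elastic fibre protein gene Fbln5 (+0.60 ± 0.18) were positive. Each of these 10 genes had an adjusted p of 1.00. By limma 0 genes passed, with 193 at an unadjusted p under 0.05 where 516 would by chance, and limma-voom gave 0, with 214. Across the 10317 genes, which are not independent replicates, the HDCA effects in the models had a Pearson r of -0.229 and a Spearman rho of -0.191, with the same sign in 41.1%. No library is shared between these effects.

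**Figure D3:**
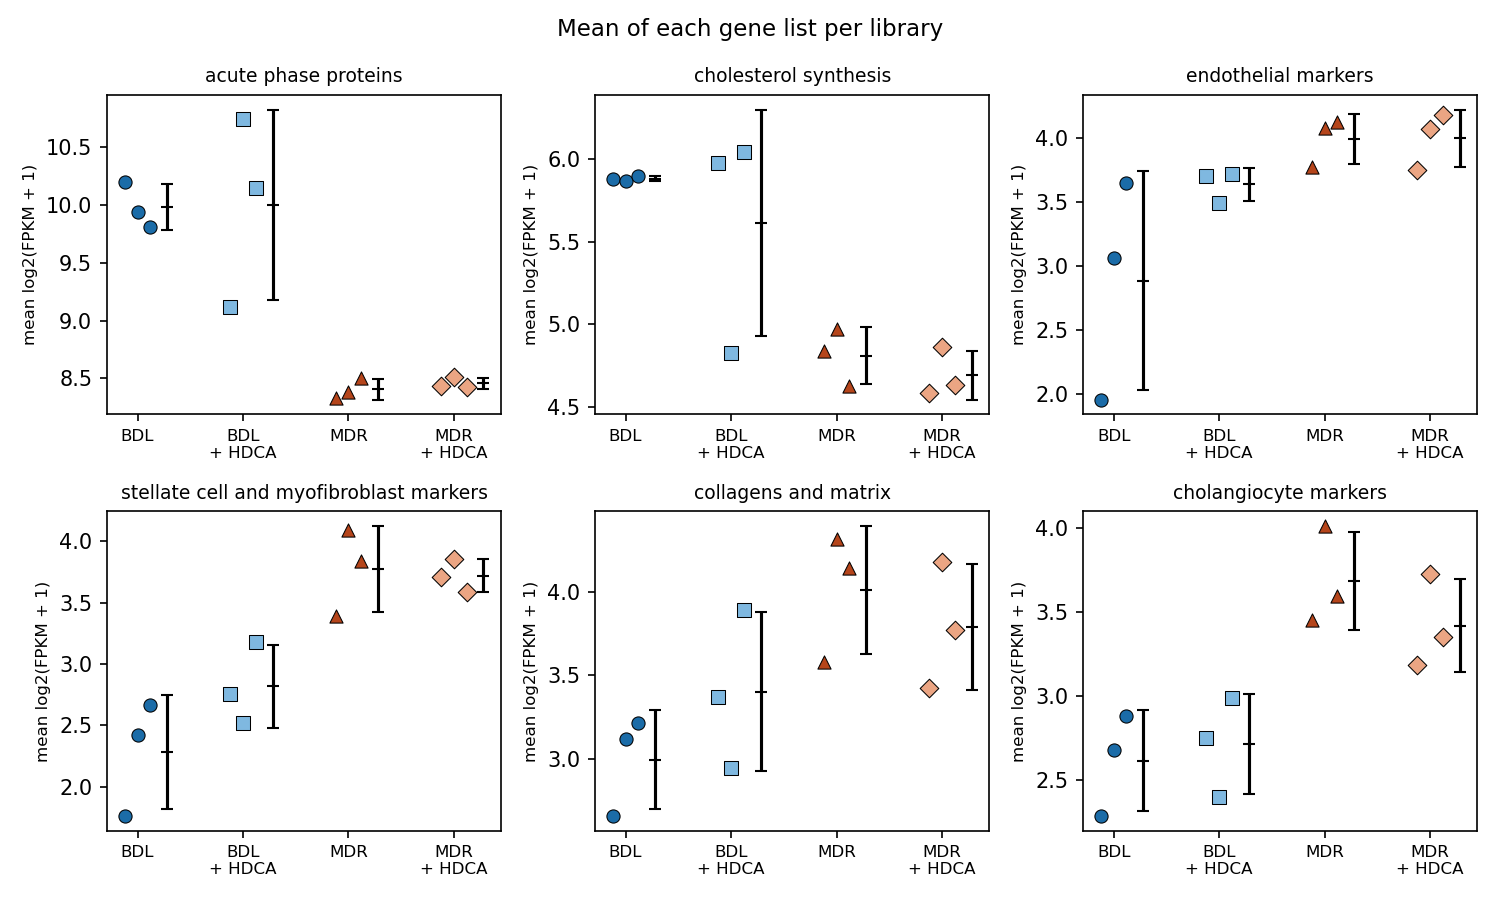
Mean log2(FPKM + 1) of 6 gene lists in each library, by group, with the group mean and SD beside the points. BDL 1 has the lowest endothelial mean (1.96), and BDL HDCA 2 has a cholesterol synthesis mean of 4.82 against 5.98 and 6.04 in the other treated ligated livers.

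Untreated ligated livers differed widely from untreated MDR-labelled livers. Acute phase proteins and cholesterol synthesis genes were higher in the ligated livers, and markers of stellate cells, endothelium, bile ducts and matrix were lower, by camera with a preset correlation. With an estimated correlation the acute phase list passed (adjusted p = 0.0488), and the others did not (adjusted p = 0.0507 for cholesterol synthesis, 0.276 for stellate cells, 0.526 for endothelium, 0.409 for bile ducts and 0.551 for matrix). The median difference of all genes, ligated minus MDR-labelled, was -0.25 on the log2 scale, and the log2 differences of this comparison are given relative to that median. The adjusted p, calls and counts of single genes are for the differences before this subtraction. The value printed for a gene is therefore not the one tested, and calls of lower genes rest in part on the shift of all genes. The metallothionein genes Mt2 and Mt1 were higher by 4.30 ± 0.74 and 3.74 ± 0.80, with Mt2 at 902 ± 634 FPKM in ligated and 43.6 ± 13.9 FPKM in MDR-labelled livers. The serum amyloid genes Saa1, Saa2 and Saa3 were higher by 3.45 ± 0.74, 3.51 ± 0.92 and 2.65 ± 0.63, and Saa1 averaged 1468 ± 720 against 148 ± 28.6 FPKM. Prtn3 had the smallest adjusted p (2.83e-06), at 12.6 ± 1.77 against 0.325 ± 0.247 FPKM, higher by 3.61 ± 0.16.

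Also among the 10 largest increases were the iron-binding lipocalin Lcn2 (+2.90 ± 0.58), the acute phase glycoprotein gene Orm2 (+2.87 ± 0.42) and the neutrophil chemokine Cxcl1 (+2.82 ± 0.40). The 10 largest decreases were led by Ccl21a (-3.49 ± 0.28), at 0.748 ± 0.378 FPKM in ligated and 23.0 ± 9.00 FPKM in MDR-labelled livers. Of these, 4 are genes of MHC class II antigen presentation, H2-Eb1 (-2.94 ± 0.45), H2-Aa (-2.60 ± 0.47), H2-Ab1 (-2.51 ± 0.49) and the invariant chain Cd74 (-2.36 ± 0.45). The matrix proteins Dpt (-2.87 ± 0.32), Sparcl1 (-2.79 ± 0.30) and Lum (-2.32 ± 0.42), the thyroid hormone deiodinase Dio1 (-2.70 ± 0.42) and the lysozyme gene Lyz1 (-2.54 ± 0.37) completed them. The adjusted p of these 20 genes ranged up to 0.0384 (Saa2). Krt19 was also lower (-0.93 ± 0.28, adjusted p = 0.0198). Nr0b2 was at +1.43 ± 0.44 (adjusted p = 0.0896), Slc51b at +0.93 ± 0.48, Cyp7a1 at +0.53 ± 0.57, Abcb11 at +0.29 ± 0.42, Cyp8b1 at -0.21 ± 0.58, Col1a1 at -0.59 ± 0.43, Timp1 at -0.40 ± 0.31, Acta2 at -0.05 ± 0.45 and Abcb4 at -0.32 ± 0.41, none of which passed. Reads of near-identical family members, such as Saa1 and Saa2, Ccl21a and its copies, Hba-a1 and Hba-a2, or Cyp2c40 and Cyp2c69, could be split or lost by the counting, so single values in these families are uncertain.

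**Figure D4:**
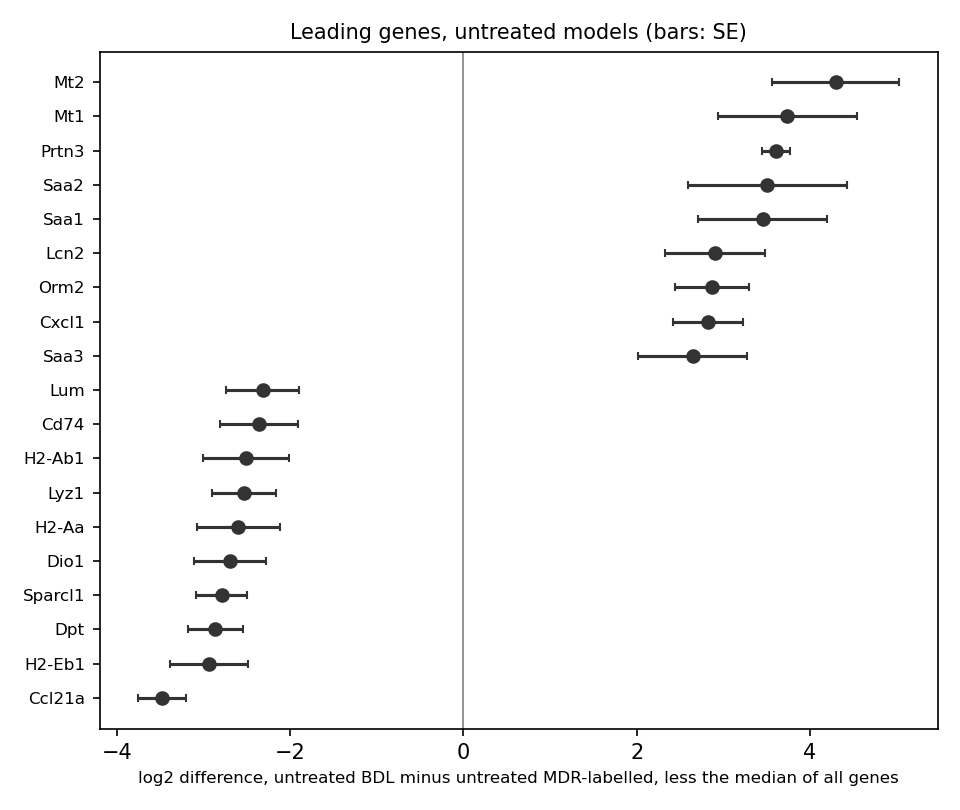
Log2 difference on log2(FPKM + 1), untreated ligated minus untreated MDR-labelled livers (n = 3 each), less the median of all genes, for 19 of the 20 largest increases and decreases past the threshold. Points are estimates from limma and bars are SE, from Mt2 at +4.30 to Ccl21a at -3.49.

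Acute phase proteins were higher in ligated livers in 11 of 18 members over all genes, and in 17 adjusted over the list alone, with a list median of +1.56 relative to all genes. This list passed camera (adjusted p = 4.38e-28, and adjusted p = 0.0488 with an estimated correlation). Cholesterol synthesis genes were higher in 14 of 24 members over all genes and in 19 adjusted over the list alone, with a median of +1.30. That list also passed camera (adjusted p = 3.98e-37), with adjusted p = 0.0507 with an estimated correlation. Among its members, the epoxidase Sqle averaged 68.7 ± 6.81 against 20.3 ± 4.45 FPKM (+1.97 ± 0.22). ER stress genes were higher in 4 of 15 members, both over all genes and adjusted over the list alone (median +0.46, adjusted p = 3.98e-08, and adjusted p = 0.198 with an estimated correlation). Before subtraction of the median of all genes, the ER stress median was +0.22, with +0.12 without BDL 2 and +0.34 without BDL 3. The 4 genes were Herpud1 (+1.73 ± 0.21), the asparagine synthetase gene Asns (+2.20 ± 0.38), the transcription factor Atf4 (+1.03 ± 0.16) and Chac1 (+1.76 ± 0.36).

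Stellate cell and myofibroblast markers were lower in ligated livers in 11 of 14 members over all genes and in 13 adjusted over the list alone (median -1.27, adjusted p = 5.24e-07, and adjusted p = 0.276 with an estimated correlation). The pericyte gene Rgs5 (-2.16 ± 0.30) and the proteoglycan gene Dcn (-1.57 ± 0.24) were among them. Endothelial markers were lower in 6 of 11 and in 9 adjusted over the list alone (median -0.93, adjusted p = 0.00485, and adjusted p = 0.526 with an estimated correlation), among them Vwf (-0.94 ± 0.21) and Kdr (-1.16 ± 0.36). Cholangiocyte markers were lower in 7 of 11, both over all genes and adjusted over the list alone (median -0.87, adjusted p = 0.00186, and adjusted p = 0.409 with an estimated correlation). Of these, Epcam averaged 3.18 ± 0.852 against 13.1 ± 3.23 FPKM (-1.50 ± 0.25), and Cd24a was at -1.82 ± 0.30. Collagens and matrix genes were lower in 8 of 18 and in 12 adjusted over the list alone (median -0.72, adjusted p = 0.00736, and adjusted p = 0.551 with an estimated correlation), led by the gelatinase gene Mmp2 (-1.77 ± 0.35). Respiratory chain genes were lower in 12 of 14 and in 14 adjusted over the list alone (median -0.28, adjusted p = 1.08e-06, and adjusted p = 0.302 with an estimated correlation), among them Ndufv1 (-0.39 ± 0.12). Globins and other erythroid markers were lower in 3 of 5 and in 4 adjusted over the list alone (median -0.91, adjusted p = 0.0404, and adjusted p = 0.526 with an estimated correlation). Interferon response genes were lower in 3 of 14 and in 10 adjusted over the list alone (median -0.61, adjusted p = 0.0215, and adjusted p = 0.611 with an estimated correlation). The erythroid call ended without BDL 1 (adjusted p = 0.119), and the interferon call without BDL 1 or MDR 3 (adjusted p = 0.119 and 0.0659) and with a filter at 5 FPKM (0.156). Before subtraction of the median of all genes, the endothelial median was -0.68 without BDL 1, against -1.17 with all libraries.

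A further 8 lists passed camera as higher in ligated livers with medians, relative to all genes, of +0.09 to +0.36. CAR and PXR targets (median +0.30, adjusted p = 4.77e-04, and adjusted p = 0.0488 with an estimated correlation) had the haem synthesis gene Alas1 (+1.90 ± 0.43) and Cyp2a5 (+1.29 ± 0.24) higher and Aldh1a1 (-0.36 ± 0.14) lower. Adjusted over the list alone the counts were also 2 higher and 1 lower. NRF2 targets had a median of +0.36 with 0 of 13 genes past the threshold by limma, over all genes or adjusted over the list alone (adjusted p = 8.58e-05, and adjusted p = 0.355 with an estimated correlation). Bile acid and biliary lipid transport had a median of +0.24 and 0 of 12 genes (adjusted p = 0.00186, and adjusted p = 0.276 with an estimated correlation). Bile acid receptors and nuclear receptors had a median of +0.14, with Nr1i2 higher (+0.73 ± 0.14) and Ppara lower (-0.41 ± 0.19), and also 1 and 1 adjusted over the list alone (adjusted p = 0.00736, and adjusted p = 0.111 with an estimated correlation). Circadian clock genes had a median of +0.25, with Per2 higher (+0.89 ± 0.16) and Npas2 lower (-1.1 ± 0.22), and 2 and 2 adjusted over the list alone (adjusted p = 0.00402, and adjusted p = 0.103 with an estimated correlation). Fatty acid and triglyceride synthesis (median +0.22, adjusted p = 0.00485), male-biased liver genes (+0.24, adjusted p = 0.00664) and the cell cycle (+0.09, adjusted p = 0.0102) had 0 genes past the threshold by limma, over all genes or adjusted over the list alone. Their adjusted p was 0.526, 0.526 and 0.619 with an estimated correlation. Without subtraction of the median of all genes, the medians of the transport, receptor, fatty acid synthesis, male-biased and cell cycle lists were negative (-0.00, -0.10, -0.03, -0.01 and -0.16), opposite to the test. These lists and the CAR and PXR and circadian lists did not pass under median-of-ratios or quantile scaling. The receptor and circadian calls ended without BDL 1 (adjusted p = 0.300 and 0.280), the cell cycle call without BDL 2 or BDL 3 (adjusted p = 0.0592 and 0.518), and the male-biased call without MDR 2 or MDR 3 (adjusted p = 0.266 and 0.0777). Where calls held, the unshifted medians without BDL 1 were +1.06 for male-biased genes, +0.50 for NRF2 targets, +0.49 for the cell cycle, +0.35 for fatty acid synthesis, +0.22 for CAR and PXR targets and +0.08 for transport, which was at -0.11 without BDL 3. The NRF2 median turned to -0.07 without BDL 3. The fatty acid synthesis median was -0.19 without BDL 2, -0.12 without BDL 3, -0.15 without MDR 2, -0.05 without MDR 3 and +0.12 without MDR 1. The male-biased median was +1.04 without MDR 1, whose male-biased mean is 7.80, and -0.64 and -0.62 without BDL 2 and BDL 3. The receptor median was +0.05 and the circadian median +0.15 without BDL 2. The cell cycle call also ended with a pseudocount of 0.1 (0.0637), and the circadian call with a filter at 5 FPKM (0.225).

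In all, limma called 1492 of 10317 genes between the untreated models, 107 higher and 1385 lower in ligated livers, 7.17% higher. With median-of-ratios scaling the split was 462 higher and 530 lower (46.6% higher), and with quantile normalization 380 and 518 (42.3% higher). Of the 1492, 470 differed at least 2-fold, and groups did not overlap for 41.8% of genes, where chance gives 10%. The count fell to 406 without MDR 2, 568 without MDR 3 and 690 without BDL 2, and was 2078 without BDL 1 and BDL HDCA 2 together. Y-linked transcripts are in all 3 untreated ligated libraries and in MDR 1 alone of the MDR-labelled ones, so these transcripts and the model were not separated here. The 20 leading genes kept call and direction under every scaling tried. In the leave-one-out fits 15 to 19 did. The calls that ended in these fits or by limma-voom were Saa2 (adjusted p = 0.0657 without MDR 1, 0.133 without MDR 2, 0.0974 without MDR 3, 0.109 without BDL 1 and 0.0735 without BDL 2), Saa3 (0.118 by limma-voom, 0.0550, 0.0988 and 0.0868 without MDR 1, MDR 2 and MDR 3, and 0.0847 and 0.0668 without BDL 2 and BDL 3) and Saa1 (0.0820 without MDR 2, 0.0585 without MDR 3 and 0.0543 without BDL 1). Others were Mt1 (adjusted p = 0.0515 without MDR 1, 0.0601 without MDR 2, 0.0503 without BDL 1 and 0.0559 without BDL 2) and Lcn2 (0.0509 without MDR 2). The Krt19 call ended without MDR 2 (0.0852) and BDL 2 (0.0530), and under median-of-ratios and quantile scaling (0.0771 and 0.0591).

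Calls of other genes named from the lists of the untreated comparison also ended in some fits. Alas1 had adjusted p = 0.0845 without BDL 1, 0.0749 without BDL 2, 0.0802 without MDR 1 and 0.124 without MDR 2, 0.0513 without BDL 1 and BDL HDCA 2 together, and 0.0874 with the compared groups alone. Cyp2a5 had 0.0519 without BDL 1, and 0.0512, 0.0685 and 0.0543 without MDR 1, MDR 2 and MDR 3. Aldh1a1 had 0.0659 and 0.0686 without MDR 2 and MDR 3, and 0.397 under median-of-ratios scaling. Nr1i2 had 0.0808 to 0.145 without BDL 1, BDL 2, BDL 3, MDR 1, MDR 2 or MDR 3, and 0.0637 as TPM. Ppara had 0.0759 to 0.139 without BDL 2, BDL 3, MDR 1, MDR 2 or MDR 3, 0.0540 to 0.435 under the other scalings and 0.0620 with the compared groups alone. Per2 had 0.0513 to 0.0799 without BDL 1, MDR 1, MDR 2 or MDR 3, and 0.0719 with the compared groups alone. Kdr had 0.0541 to 0.0953 without BDL 1, BDL 2, MDR 1, MDR 2 or MDR 3, 0.0511 under median-of-ratios scaling and 0.0915 with the compared groups alone. Chac1 had 0.0505, 0.0547 and 0.0910 without BDL 2, MDR 1 and MDR 2, and 0.0725 with the compared groups alone. Ndufv1 had 0.408 and 0.0698 under median-of-ratios and quantile scaling. The direction of each stayed in these fits.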

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

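The tests of explanations and the counts over other splits in this part were chosen after the results were seen, whereas the list tests themselves were planned.

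A test of the difference of the HDCA effects between models passed in 9 gene lists with a preset correlation, which is why these are listed here. With an estimated correlation none of the 9 passed by camera (adjusted p = 0.81), and by fry 0 lists passed. The list medians of the difference, ligated minus MDR-labelled, were 0.945 for erythroid markers, 0.751 for endothelial markers, 0.622 for collagens and matrix, 0.507 for stellate cell and myofibroblast markers, 0.366 for cholangiocyte markers and 0.126 for the respiratory chain. They were -0.104 for acute phase proteins, -0.105 for cholesterol synthesis and 0.0564 for ER stress, whose test direction was lower. The preset-correlation count does not exclude chance: 67 of 100 splits of the samples gave at least as many lists, with 9 in the real split and 16 in the highest other one. These splits took no account of possible pairs among the MDR-labelled samples. For genes the real count by limma was 0 (193 at an unadjusted p under 0.05, and 0 by limma-voom), so all 100 of 100 splits had to give as many, which decides nothing. The highest other count was 0.

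With 3 samples against 3 there are 10 splits, too few for a share under 0.05. For HDCA in ligated mice, 10 of 10 splits gave as many lists, with 6 in the real split and 14 in the highest other. The splits with 14, 13 and 13 lists put BDL 1 and BDL HDCA 2 on the same side, which points to a structure of the samples other than treatment. For genes, 10 of 10 splits gave 0 by limma (229 at an unadjusted p under 0.05 in the real split, and 0 by limma-voom), which likewise decides nothing. For HDCA in MDR-labelled mice, 5 of 10 splits gave as many lists, with 8 in the real split and 11 in the highest other. Here the numbers may pair the samples, and the other splits that part all 3 pairs gave 2, 3 and 9 lists, while those that keep a pair together gave 4 to 11. For genes, 10 of 10 splits gave 0 by limma (51 at an unadjusted p under 0.05 in the real split, and 0 by limma-voom), and again this decides nothing. Between the untreated models, 1 of 10 splits gave as many genes, the real one with 1492 and the highest other with 16. For lists there, 2 of 10 did, with 18 in the real split and 19 in the highest other.

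The higher endothelial, stellate cell and collagen lists with HDCA in ligated mice may come from the libraries that stand apart, from a lower share of hepatocytes, or from the treatment. Without BDL 1 and BDL HDCA 2 the 3 calls held with the preset correlation (adjusted p = 3.57e-05, 1.30e-05 and 1.30e-05, and adjusted p = 0.528 with an estimated correlation), and the list mean differences were 0.36 ± 0.29 (SE), 0.43 ± 0.24 and 0.46 ± 0.27, against 0.75 ± 0.50, 0.54 ± 0.33 and 0.40 ± 0.32 with all libraries. The smallest is 1.23 SE, so with 2 libraries per group a contribution of those left out cannot be told apart from treatment. A lower share of hepatocytes would raise markers of all other cell types alike, whereas the endothelial list difference lay above that of the macrophage list by 0.59 ± 0.36 (SE) and above that of the cholangiocyte list by 0.66 ± 0.34, the smaller gap being 1.63 SE, too little to decide. An effect of HDCA on these cells, on their number or their expression, stays open and untested.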

How the results depend on the processing

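Alternatives added after the data were seen are leaving out BDL 1 with BDL HDCA 2, the term for Y-linked transcripts, the block with 1 MDR-labelled pair left out, limma-voom, further scalings of the lists and gene-by-gene array weights; all others were planned. Of the counts of calls over all settings, 136 stayed within 1.5 times, 27 were lower and 10 higher. Many of the 136 were counts of 0 genes in both fits, which say nothing of how stable a call is. Of list results 513 kept direction and call, 205 lost the call and 15 turned. Of results for named genes, each a gene in 1 comparison and 1 setting, 4975 stayed the same, 197 lost the call, 72 gained it, 124 moved and 1 turned. A called gene stayed the same if it kept its call and direction. A gene called in neither fit stayed the same if it shifted by less than the residual SD, and moved otherwise, whatever its direction. Turns were therefore counted only among genes called in at least 1 of the fits. For HDCA in either model and the difference of effects, every setting gave 0 genes by limma and limma-voom except array weights, with 1 gene in ligated mice by both methods, and the block without MDR-labelled pair 1, with 1 gene (229, 51 and 193 at an unadjusted p under 0.05 in the reported fits). Fewer genes or libraries enter some settings, and beyond that the cause was not tested.

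Between the untreated models, 1492 genes became 2248 with no filter, 616 with a filter at 5 FPKM, 992 with median-of-ratios scaling, 898 with quantile normalization, 614 with the compared groups alone, 470 with a fold threshold and 11 with the Y-linked term. That term leaves MDR 1 as the only untreated MDR-labelled library, so what it ended between these models says nothing of how stable the calls are. Array weights gave 4670 genes, although their estimation stopped before converging, and 3751 by the gene-by-gene method. With array weights Cyp7a1 turned to -0.79 (adjusted p = 0.0324, against 0.737 unweighted). Leaving out 1 library gave 406 (without MDR 2) to 1491 genes (without BDL 3), the reduced group being assumed to vary like the others.

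With an estimated correlation 0, 0, 0 and 2 lists passed for HDCA in ligated mice, HDCA in MDR-labelled mice, the difference and the untreated models, and with fry 0, 0, 0 and 8. By fry's direction, which does not compare a list with other genes, the bile acid receptor (median -0.105), cell cycle (-0.157), circadian (0.00739) and fatty acid synthesis (-0.0289) lists turned between the untreated models. The cell cycle list also turned with median-of-ratios scaling (0.11), and the male-biased list with the Y-linked term (-1.97), where MDR 1 stands alone. For HDCA in MDR-labelled mice, 8 lists became 4 with quantile normalization, 3 with median-of-ratios scaling and 4 with the Y-linked term, which there equals leaving out MDR 1. With the block and pairs 1, 2 and 3 left out in turn, 13, 4 and 6 lists passed there. Without BDL 1 and BDL HDCA 2, 12 lists passed for HDCA in ligated mice, and the cholesterol synthesis median turned to 0.11 there and to 0.27 for the difference.

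Leaving out 1 library gave 5 to 15 lists for HDCA in ligated mice, 2 to 7 for HDCA in MDR-labelled mice and 4 to 13 for the difference. Over these fits the cholesterol synthesis median ran from -0.59 to 0.10 in ligated mice and from -0.39 to 0.22 for the difference, and the acute phase median from -0.36 to 0.18 for the difference. In MDR-labelled mice the medians ran from -0.44 to -0.057 for collagens, -0.029 to 0.16 for glucose metabolism, -0.085 to 0.22 for PPAR alpha targets and -0.17 to -0.025 for the respiratory chain.

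With the replicate block, 0, 0, 0 and 1134 genes passed in the same order, and 6, 7, 8 and 19 lists. Same-numbered samples correlated by -0.434, -0.386 and 0.440 in the ligated groups and by -0.204, -0.151 and -0.252 between the untreated models, so they share only a number there. Not every ligated sample correlated best with its own number. In the MDR-labelled groups, where the numbers may mark pairs, the block changed no call but that of the respiratory chain (adjusted p = 0.0941). For the difference, only the MDR-labelled side showed a sign of pairs. With the block its acute phase and respiratory chain calls ended (0.0711 and 0.0743), the male-biased list passed (0.0228) and the other 7 calls stayed. Of the 20 leading genes between the untreated models 19 kept their call, Saa2 having adjusted p = 0.0648. Planned but not run were a protein-coding subset, for which the table gives no biotype, and limma-voom with given lengths, replaced by solved lengths. Depth limits values near 0.0247 to 0.0292 FPKM per kilobase, below the filter.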

Other observations

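All tests of explanations in this part were chosen after the results were seen, while the list tests were planned.

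Lists that passed in no comparison by camera are given here as values. Bile acid synthesis genes had medians of +0.08 with HDCA in ligated mice (adjusted p = 0.823) and +0.05 in MDR-labelled mice (adjusted p = 0.226). Between the untreated models the list median was +0.34 relative to all genes (adjusted p = 0.0516), with 2 genes lower over all genes and 3 adjusted over the list alone. Macrophage and monocyte markers had medians of +0.13 (adjusted p = 0.567) and -0.04 (0.569) with HDCA. Between the untreated models they were at -0.39 (0.537), with 2 genes lower over all genes and 6 adjusted over the list alone. Cytokines, chemokines and adhesion molecules had medians of +0.28 (0.222) and -0.09 (0.569) with HDCA, LXR targets +0.04 (0.823) and +0.01 (0.303), and the m6A list +0.04 (0.925) and -0.04 (0.569). Between the untreated models these were at -0.09 (0.209), +0.08 (0.241) and +0.09 (0.968). Lists with under 5 expressed members were not tested: neutrophil and female-biased liver genes with 4 each, T, B and NK cell markers with 3, adipocyte markers with 1 and pancreatic acinar markers with 0.

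Sex-biased liver genes varied within groups. BDL 1, which has Y-linked transcripts, had a mean of 3.66 for female-biased genes, against 0.520 to 1.43 in the other 5 ligated libraries. Its male-biased mean was 3.95, against 5.92 to 6.61 in those 5. MDR 1 had means of 0.396 and 7.80 for the female-biased and male-biased lists, and the other 5 MDR-labelled libraries had 1.44 to 4.92 and 3.99 to 6.17.

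Abcb4 transcript in the MDR-labelled libraries has a technical or a genetic explanation. No ligated library lacked the transcript either (lowest 52.8 FPKM). This argues against labels swapped between the models only if the null allele makes no transcript. With an allele that still makes one, the value cannot speak to a swap. The paralogs Abcb1a and Abcb1b reached at most 3.70 FPKM in the MDR-labelled libraries. This cannot decide whether their reads were counted as Abcb4, because such reads would be missing from the paralog values. An allele that still makes a transcript may account for the Abcb4 values. The difference of untreated ligated minus MDR-labelled livers, before subtraction of the median of all genes, was -0.56 ± 0.41 (SE), which cannot tell this from mice with an intact gene.

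Cyp2c40 and Cyp2c69 were higher with HDCA in the MDR-labelled libraries, without passing the test. Without MDR 1, the one with Y-linked transcripts, the differences were 2.47 ± 0.96 (SE) for Cyp2c40 and 2.79 ± 1.2 for Cyp2c69. These equal 2.56 SE for Cyp2c40 and 2.34 SE for Cyp2c69. With MDR 1 they were 3.30 ± 0.96 and 3.35 ± 1.08. With the replicate number as a block and pair 1 left out they were 3.46 (adjusted p = 1.00) and 4.08 (adjusted p = 0.00485). These differences do not decide whether the sex mix of the libraries is the whole cause, because both genes were named for their small p in these same libraries. Among the 5 MDR-labelled libraries without Y-linked transcripts, the female-biased list mean also ran from 1.44 to 4.92. A library without Y-linked transcripts swapped into the ligated groups is argued against, since 0 of the 6 ligated libraries lack them. This cannot show a swap of libraries that have them, as MDR 1 does. The sex mix in whole or in part, a chance difference between single mice and an effect of HDCA on these genes stay open.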
